A study of Mus musculus with 5 samples.

How the data were processed

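The series holds 5 single-cell RNA libraries from mouse bone marrow, 3 from young mice (10 to 12 weeks, replicates 1, 2 and 3) and 2 from aged mice (over 20 months, replicates 2 and 3). All mice carried a Nestin-GFP reporter. Per the labels, cells negative for CD45 (a surface protein of blood cells) and positive for CD31 (PECAM1, a junction protein of endothelium) were sorted from endosteal preparations, that is, from the inner bone surface. The sorted cells were frozen, thawed and loaded on a droplet system that tags each RNA molecule at its 3' end with a cell barcode and a unique molecular identifier (UMI). The number of PCR cycles was set for each library separately, per the labels' protocols.

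The deposited values are raw UMI counts per gene and cell barcode, 1 table per library with 27998 Ensembl genes. Per the submitters' processing notes, Cell Ranger and the mouse build mm10 were used, and R 3.5.2, edgeR 3.24.3 and DESeq2 1.22.2 are also named by the submitters without a role. The Cell Ranger version and the rule that chose the deposited barcodes are not given in the sources used here. All columns of the 5 tables were used. Gene symbols came from a reference table of gene names that matched 27645 of the 27998 identifiers. Positions of named genes came from GENCODE release M21 on GRCm38. Immunoglobulin constant region genes were not used here.

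A barcode entered with at least 500 detected genes, at least 1000 UMIs and at most 10% of UMIs from the 13 mitochondrially encoded genes, which kept 2116 of 3384 barcodes. Total UMIs per library ranged from 935656 to 5900751, and the median UMIs of a kept cell ranged from 1889.5 to 4212.5. Counts were scaled to a common total per cell and log transformed. The 2000 most variable genes, 30 principal components, 15 nearest neighbours and Leiden clustering (leidenalg 0.10.2, resolution 0.8) gave 9 clusters, numbered 0 to 8 by size. Doublets were called per library with the Scrublet routine of scanpy 1.11.5 at an expected rate of 2%, which marked 27 kept cells. They stayed in the main analysis and were left out as an alternative. Clusters were named from 21 marker lists, with a marker taken as detected when at least 10% of a cluster's cells held a UMI of it.

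Cells are not replicates, so counts were summed per library and cell class and the libraries were compared. The main test was edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. The standard error of a log2 fold change was taken as its size divided by the square root of F. Gene lists with at least 3 measured members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. Shares of cells were compared with a two-sided exact permutation test over the 10 ways to choose the 2 aged libraries. The smallest p that this exact permutation test can give is 0.1, so no share can pass a threshold of 0.05. A cell counted as cycling with at least 2 of 10 cell cycle genes detected after thinning each cell to 1000 UMIs. Intervals of shares are exact binomial (Clopper-Pearson, 95%) and cover counting error only, and a count of 0 was bounded by 3 cells.

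The endothelial comparison, the 25 gene lists, the marker lists, the filters and the alternatives for the endothelial results were fixed before the data were examined. Of 8 planned comparisons, 4 gave values. Sinusoidal and arterial cells could not be compared separately, because the endothelial cells formed 1 cluster and no library held 10 of them. The names of the clusters, every comparison within the B lineage, the shares of neutrophil-like, dividing and cluster 3 cells, and a term for sex-linked transcripts were chosen after seeing the data. In all, 13 comparisons were made, 5 of genes, 2 of gene lists and 6 of shares. They were repeated under 25 alternative settings where these applied, which gave 172 further values. The alternatives changed the test (DESeq2 1.42.0 or limma), the scaling, the filters on genes and barcodes, doublets, depth, cluster resolution, the block of replicate numbers and the libraries included.

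Genes named in the endothelial-like and B-lineage comparisons were the 10 of largest change in each direction among those past the threshold with a mean log2 CPM of at least 5 and every aged library outside the young range. Where fewer passed, the genes of smallest p filled the number, and they are described as not passing. The comparisons within B-lineage clusters used 5 genes in each direction. For each gene list up to 3 measured members of smallest p were taken, of which the text gives a part, and Jag1, Jag2, Dll1 and Dll4 were always included. Some other genes that these rules name are not reported here.

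The procedure was tested on simulated counts with known changes. At a 2-unit log2 change it recovered 97% of changed genes for the non-dividing B-lineage sums (6207 genes), 95% for cluster 3 (3477 genes), 97% for clusters 0 and 1 (4587 genes) and 75% for the endothelial-like sums (45 genes). At a 1-unit log2 change the recovery was 20%, 24%, 30% and 14.3% in the same order. The numbers in brackets are the genes tested, not the genes changed. The changed genes numbered 200, 200, 200 and 15 in all, so the endothelial-like percentages rest on few genes. The changed genes were drawn only from genes above the median of mean expression. All genes of a class were given 1 common spread, and 1 simulation was made per class. The percentages describe the changed genes only, and recovery may differ for genes of other expression or spread. False calls were 4 of 121, 3 of 122, 9 of 136 and 1 of 8 calls, and the median estimate of a 2-unit change was 2.00, 1.99, 1.99 and 2.78. Libraries of 1 group were checked for duplication: the chi-square per degree of freedom between their counts lay between 7.26 and 55.8, where sampling noise alone gives about 1, so each library was counted once. The labels speak of biological replicates but do not name animals, so p-values measure the spread between these libraries.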

Results

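The libraries were made to compare endothelial cells of young and aged bone marrow, the cells that line marrow vessels and carry signals to blood stem cells. They held 1002, 329 and 746 barcodes in young replicates 1, 2 and 3 and 385 and 922 in aged replicates 2 and 3. Total UMIs were 5900751, 935656 and 1003476 in the young libraries and 1025884 and 1312911 in the aged. After the filter 890, 226, 316, 282 and 402 cells remained in the same order, with medians of 4212.5, 2748, 2015.5, 2866.5 and 1889.5 UMIs. Sex-linked transcripts split the libraries by replicate number. Xist, expressed from the inactive X chromosome, gave 8562, 1118 and 1672 UMIs in young replicates 1 and 3 and aged replicate 3, and 0 in both libraries of replicate 2. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d together gave 224 and 284 UMIs in young and aged replicate 2 and at most 1 elsewhere.

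Most cells in these libraries were of the B lineage. B-lineage cells made up 79.7% (95% interval 76.9 to 82.3), 98.7% (96.2 to 99.7) and 98.1% (95.9 to 99.3) of young replicates 1, 2 and 3, and 99.6% (98.0 to 99.99) and 96.0% (93.6 to 97.7) of aged replicates 2 and 3. Of the 2116 cells, 1188 (56.1%) lay in 4 non-dividing B-lineage clusters and 721 (34.1%) in 3 dividing ones. Cd79a, a part of the B cell receptor complex, was detected in 96.0% of the non-dividing cells and Ebf1, a transcription factor that specifies the B lineage, in 99.7%. In the endothelial-like cells Cd79a was detected in 22.2% and Ebf1 in 55.6%, and the source of these UMIs was not decided. Median depths were 2244 UMIs in the non-dividing and 2594 in the endothelial-like cells. Cluster 3 was led by Vpreb1, Igll1, Vpreb2 and Dntt, genes of the surrogate light chain and of receptor rearrangement in early B cells. Clusters 0 and 1 were led by Cd74 and H2-Aa and by Ms4a1 and Cd2, which rise later in B cell development.

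Endothelial-like cells were 18 of 2116 (0.851%), with 7, 1 and 1 in young replicates 1, 2 and 3 and 1 and 8 in aged replicates 2 and 3. All 14 pan-endothelial markers were detected in at least 10% of them. A UMI in 2 of 18 cells, as for the arterial markers Gja4 and Sema3g, meets this rule. It was also met by 7 of the 8 B cell markers and by 3 pan-leukocyte markers. Cdh5, the cadherin of endothelial junctions, had a UMI in 100% of endothelial-like cells against 0.253% of non-dividing B-lineage cells. Their leading genes were Fabp4, Ly6c1, Igfbp7, Ly6a, Gpihbp1, Cav1 and Aqp1. Among subtype markers, 15 of the arterial list were detected in at least 10% of these cells and 6 of the sinusoidal list, while Stab2, a scavenger receptor of sinusoids, had a UMI in 0 of 18, which allows a share of cells with a UMI of up to 16.7% and does not limit the share of cells that express it. Ptprc, the gene of CD45, also had a UMI in 0 of 18, against 27.4% of non-dividing and 35.5% of dividing B-lineage cells. Pecam1, the gene of CD31, had a UMI in 94.4% of endothelial-like, 27.9% of non-dividing and 24.7% of dividing B-lineage cells.

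**Figure D1:**
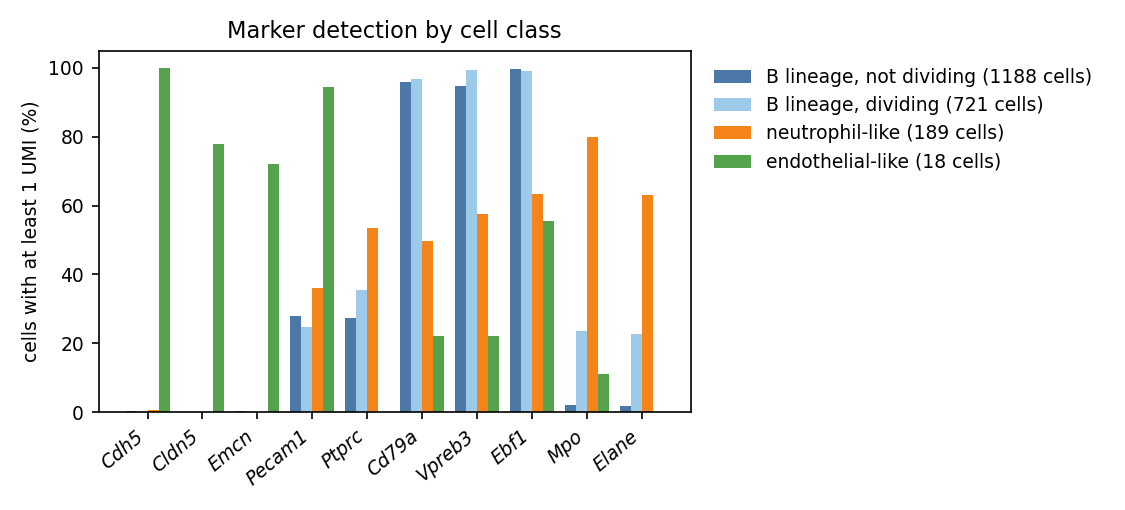
Share of cells (%) with at least 1 UMI of each gene, with 1 bar per cell class over all 5 libraries. Cdh5 was found in 100% of the 18 endothelial-like cells and Ebf1 in 99.7% of the 1188 non-dividing B-lineage cells, while Pecam1 was found in every class.

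The share of non-endothelial cells did not differ detectably with age. It was 98.8% ± 1.16 (SD, n = 2) in aged and 99.5% ± 0.243 (SD, n = 3) in young libraries (exact permutation p = 0.5). Within replicate number 2 the aged and young values were 99.6% and 99.6%, and within number 3 they were 98.0% and 99.7%. The direction rested on aged replicate 3: without it the difference, aged minus young, was 0.161 points, against -0.657 points with all libraries. No endothelial-like cell met the rule for a cycling cell (0 of 18, which allows a share of up to 16.7%). The per-library upper limits ran from 37.5% in aged replicate 3 to 100% where there was 1 cell.

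In endothelial-like cells Aqp1, a water channel of endothelium, had higher values in the aged libraries. Its log2 fold change was 3.20 ± 0.76 (SE, 3 young and 2 aged libraries, edgeR adjusted p = 0.0311), and it was the only one of 69 tested genes past the threshold. The UMIs behind it were 16, 1 and 0 in 7, 1 and 1 young cells and 4 and 78 in 1 and 8 aged cells. Aqp1 (ENSMUSG00000004655) is protein-coding and lies on chromosome 6 from 55336432 to 55348555 in GRCm38. The call was lost with DESeq2 (0 genes), with limma on mean log values (0 genes), with the replicate number as a term, and without young replicate 2 or young replicate 3 (0 genes each). In these fits Aqp1 in endothelial-like cells had log2 fold changes between 2.84, without young replicate 2, and 4.63, with the replicate number as a term. Without young replicate 1 or aged replicate 3 the filter on low counts left Aqp1 out, and 0 genes were called. In 3 of the 5 libraries the summed profile was that of 1 cell, and these sums held between 1386 and 4178 UMIs. Of the other leading genes of the class, the young replicate 3 cell had 0 UMIs of Fabp4, Cav1 and Ly6a. It had 1 of Ly6c1, 3 of Gpihbp1 and 4 of Igfbp7. A change with age therefore cannot be told apart from differences between single cells. In simulated counts for the endothelial-like sums, genes with a true log2 change of 2 had a median estimate of 2.78.

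The other genes of smallest p in endothelial-like cells did not pass. Values were higher in aged libraries for the caveolin Cav1 (log2 fold change 2.11, adjusted p = 0.226), the fatty acid receptor Cd36 (2.02, 0.594), the protease inhibitor Cst3 (1.60, 0.226), Ly6c1 (1.38), Crip1 (1.32), Ly6a (1.05), Rps28 (0.99), Ly6e (0.93) and Itm2b (0.77). Values were lower for the actin-binding Tmsb10 (-1.80, 0.226), Rps24 (-1.39), Rps15a (-1.14), Tpt1 (-0.96), Sparc (-0.79), Eef1a1 (-0.79), Rpl23 (-0.78), Rpl10 (-0.75), Rps19 (-0.58) and mt-Nd1 (-0.57). With CPM scaled over the 69 tested genes, Sparc stood at 26213 in aged replicate 2, above all young libraries (10055 to 20188). This was 7 UMIs in a cell of 1386 UMIs, against 12 in the young replicate 3 cell of 1770. Over all UMIs of each cell, young replicate 3 was higher than aged replicate 2. In aged replicate 3 Sparc was at 4319 CPM, and without that library its log2 fold change was 0.65. In all 5 genes had an unadjusted edgeR p under 0.05. The aged libraries lay outside the young range in 37.7% of the 69 genes, where chance gives 20%.

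Only 2 of the 25 gene lists had 3 measured members in endothelial-like cells. Cytosolic ribosomal protein genes fell by the preset-correlation test, with 27 of 33 members lower, 0 past the threshold alone and a median log2 fold change of -0.29 (camera adjusted p = 0.0101). The adjusted p = 0.251 with an estimated correlation, and it was 0.559 without young replicate 1. Mitochondrially encoded genes were lower in 6 of 6 members (median -0.40) and did not pass (camera adjusted p = 0.169, and 0.00726 without young replicate 1). In the same cells, scaled over all their UMIs, the 8 B cell markers together stood at 1620 CPM in young replicate 1 (20.7% of the B-lineage level). They stood at 964 CPM in aged replicate 3 (6.85%). Arterial markers reached 3 measured members when 1 library was left out, and were then called with higher values without young replicate 2 (camera adjusted p = 0.0162) and without aged replicate 2 (0.00961), but not without young replicate 3 (0.0767). Immediate early genes were called with higher values without aged replicate 2 (2.84e-06). Adjusted over the list alone, 0 members of either list passed. The lists with 1 or 2 measured members held Ly6c1 and Ly6a (arterial markers), Cd36 (scavenger receptors), Ly6e (interferon response), B2m and H2-D1 (MHC class I, 0.69 and 0.61) and Sparc (basement membrane and matrix), and none of these passed. The other 18 lists had 0 measured members, among them the Notch pathway, haematopoietic niche factors and sinusoidal markers.

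The Notch ligands were seen in a few endothelial-like cells and were too sparse to compare with age. Jag1 had a UMI in 2 of 18 endothelial-like cells and 3 of 2098 other cells, Jag2 in 5 and 6, Dll1 in 3 and 8, and Dll4 in 3 and 2. In GRCm38 Jag1 (ENSMUSG00000027276) lies on chromosome 2 from 137081456 to 137116644 and Dll4 (ENSMUSG00000027314) on chromosome 2 from 119325784 to 119335962. Jag2 (ENSMUSG00000002799) lies on chromosome 12 from 112907819 to 112929776 and Dll1 (ENSMUSG00000014773) on chromosome 17 from 15367354 to 15376872.

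Since most cells were of the B lineage, the age comparison was repeated there, a choice made after seeing the data. In non-dividing B-lineage cells no gene passed in the main fit, which had no term for the replicate number. There edgeR called 0 of 6483 genes, with 123 at an unadjusted p under 0.05, and DESeq2 and limma called 0. With that term genes were called, Cd74 and H2-Ab1 among them with lower values. With no filter on low counts and without the term 11 genes were called, 1 higher and 10 lower. Ms4a1, Ifi27l2a and Cd83 were among the lower ones. The aged libraries lay outside the young range in 16.1% of genes, where chance gives 20%. The genes of smallest p that were higher in aged libraries were the haemoglobin gene Hbb-bs (log2 fold change 3.52 ± 0.64, adjusted p = 0.639), Rassf4 (1.28), Nav2 (0.92), Abca1 (1.67), Tmem191c (1.24), Ddah2 (0.88), Maml3 (1.09), Zfp398 (0.96) and Zfp87 (1.00). Those that were lower were the activation marker Cd83 (-2.46), the B cell surface gene Ms4a1 (-2.03 ± 0.55), the interferon-induced Ifi27l2a (-1.76 ± 0.49), Prg3 (-2.03), Rexo2 (-1.84), Mtx2 (-1.32), Eaf2 (-1.24), Itga6 (-1.69), and the bone matrix genes Col1a2 (-4.61) and Bglap. Bglap and Col1a2 are on the list of bone-forming cell markers and Hbb-bs on the erythroid list. Bglap had 10, 17 and 2 UMIs in the young libraries and 0 in both aged ones, so no fold is given for it. Hbb-bs had 0, 2 and 3 UMIs in the young and 41 and 19 in the aged libraries, and Col1a2 had 10, 21 and 0 in the young and 1 and 0 in the aged.

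**Figure D2:**
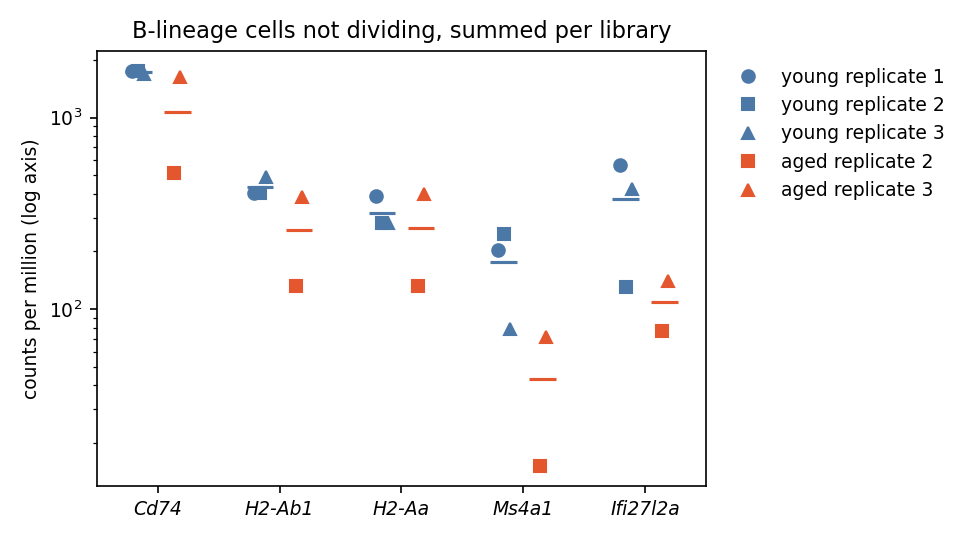
CPM (log axis) of 5 genes in non-dividing B-lineage cells summed per library; each point is 1 library, shapes mark the replicate number and lines the mean of each age group. Cd74 was at 512 in aged replicate 2 and between 1635 and 1761 in the other 4 libraries.

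MHC class II genes, which present peptides to T cells, were lower in aged non-dividing B-lineage cells, and the lower values were those of aged replicate 2. All 5 measured members had lower values (median log2 fold change -0.66, camera adjusted p = 0.00034, 0 members past the threshold without the replicate number as a term), with adjusted p = 0.811 with an estimated correlation. Cd74, the invariant chain, was at 1755, 1761 and 1683 CPM in young replicates 1, 2 and 3, at 512 in aged replicate 2 and at 1635 in aged replicate 3. H2-Ab1 was at 402, 403, 491, 132 and 384 CPM in the same order. Without aged replicate 2 the list's test turned to higher values (adjusted p = 0.853). Within clusters 0 and 1 Cd74 was at 908 CPM in aged replicate 2 and 2530 in aged replicate 3, against 2354 to 2863 in the young libraries. Cluster 0, led by Cd74, held 60.3% of the non-dividing B-lineage cells in aged replicate 3 and 13.8% in aged replicate 2, where cluster 7 held 25.9%. It held 19.6% in young replicate 2, where Cd74 was at 1761 CPM, the highest of the 5 libraries. Cd74 (ENSMUSG00000024610) lies on chromosome 18 from 60803848 to 60812652 in GRCm38.

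Of the 18 lists tested in these cells, 4 more were called, all with lower values. Cell cycle genes were lower in 10 of 12 members (median -0.66, camera adjusted p = 0.00748), among them Stmn1 (-1.47), Tuba1b (-0.84) and Rrm2 (-1.17). Heat shock genes were lower in 6 of 7 (-0.29, 0.00705), including Hsp90aa1 (-0.49) and Hspd1 (-0.54). Nuclear-encoded oxidative phosphorylation genes were lower in 31 of 35 (-0.21, 0.00705), including Ndufs6 (-0.52) and Cox6a1 (-0.33), and ribosomal protein genes in 65 of 75 (-0.14, 0.00705), including Rps12 (-0.50). No member of these lists passed alone. The adjusted p = 0.811 with an estimated correlation for the cell cycle and heat shock lists and 0.872 for the other two, and fry called 0 lists (lowest adjusted p = 0.952). Without aged replicate 2 the 4 adjusted p were 0.344, 0.716, 0.247 and 0.617. Without young replicate 1, the library with most dividing cells, they were 0.546, 0.00989, 0.556 and 0.731, and the tests of the oxidative phosphorylation and ribosomal lists turned to higher values. Without young replicate 3 the cell cycle and heat shock lists were at 0.0756 and 0.0969. With the replicate number as a block the 4 camera adjusted p were 0.245, 0.00744, 0.471 and 0.471. The oxidative phosphorylation and ribosomal lists then turned to higher values. With the term for sex-linked transcripts the 4 camera adjusted p were 0.00567, 0.0329, 0.0712 and 0.0776.

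The other 13 lists did not pass. MHC class I genes were higher in 8 of 11 members (median 0.14, camera adjusted p = 0.0537), with H2-Q6 at 0.60, H2-Q4 at 0.37 and Tap2 at 0.28; these H2-Q genes are close paralogs whose counts can be split. Unfolded protein response genes were lower in 10 of 13 (-0.21, 0.0537), with Sdf2l1 at -1.42. Endothelial identity genes (0.16, 0.0952), with Erg at 0.54 and Pecam1 at 0.16 among 5 measured members, cholesterol genes (-0.47, 0.0952) and mitochondrially encoded genes (-0.24, 0.104) followed. Senescence and p53 targets had a median of 0.11 (adjusted p = 0.474), with Cdkn1a at 0.45. Interferon response genes were at -0.03 (0.714), glycolysis and hypoxia at -0.10 (0.804), immediate early genes at -0.19 (0.861) and sex-linked transcripts at 0.56 (0.992). For 3 lists the median, mean and test differed in sign. The Notch pathway had a median of -0.00 and a mean of -0.03 with a test toward higher values (0.517). BMP and TGF-beta signalling had 0.04 and -0.06 with a test toward lower values (0.714), and NF-kappaB and activation had -0.01 and 0.04 with a test toward higher values (0.861). Leaving out 1 library turned some of these lists past the threshold. Without young replicate 1 they were unfolded protein response (adjusted p = 0.00312) and cholesterol (0.0243), and without young replicate 3 MHC class I (0.00319) and Notch (0.0410). Without young replicate 2 mitochondrially encoded genes passed (2.45e-05). Without aged replicate 3 these passed again (4.72e-05), with unfolded protein response (0.00574), BMP and TGF-beta (0.0138) and sex-linked transcripts (0.000176). Aged replicate 2, the only aged library of that fit, had 0 Xist and 284 Y-linked UMIs, so its sex-linked result cannot be read as age. With every deposited barcode MHC class I (0.0173), unfolded protein response (0.0403), glycolysis and hypoxia (0.0372) and cholesterol genes (0.0372) passed, and with doublets left out MHC class I (0.0366). Adjusted over the list alone, 1 interferon gene (Ifi27l2a) and 1 matrix gene (Sparc) passed and 0 genes of the other lists. Sparc had 12, 10 and 2 UMIs in the young and 1 in each of the aged libraries, where UMIs of the bone-forming cell markers Col1a2 and Bglap were in sum also fewer.

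The 7 lists with under 3 measured members were not tested as lists. Their members were Tgfb1 (0.50) and Csf1 (0.80) of the niche factors, Ctsl (0.19) and Dnase1l3 (0.02) of the sinusoidal markers, Glul (0.02) of the arterial markers, Cxcr4 (-0.28) of the type H and tip cell genes, Fcgr2b (0.34) of the scavenger receptors, Vegfa (0.65) of VEGF and angiopoietin signalling, and Sparc and Lamc1 (0.00) of the matrix list. None passed over all genes.

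No gene passed within early B-lineage cells (cluster 3) or within clusters 0 and 1 in the main fit, which had no term for the replicate number. A few did with that term, and 5 did in clusters 0 and 1 with no filter on low counts. In cluster 3 edgeR called 0 of 3805 genes (111 at an unadjusted p under 0.05), and DESeq2 and limma 0. The genes of smallest p were Rpl36-ps3 (log2 fold change 1.05), the interleukin 7 receptor Il7r (1.36), Hmgn5 (1.40) and Nipsnap3b (1.28), and Ifi27l2a (-1.50), Cd69 (-1.04), Stmn1 (-1.27), Lgals1 (-1.03) and Snhg12 (-1.19). In clusters 0 and 1 edgeR called 0 of 4823 (104 at an unadjusted p under 0.05), and DESeq2 and limma 0. There the genes were Rassf4 (1.30), Ykt6 (1.63), Ttc33 (1.27), Mlxip (0.91) and Akap8l (0.95), and Ms4a1 (-1.91), Cd83 (-2.37), Ifi27l2a (-2.04), Prg3 (-1.69) and Mycbp (-1.56). Calls appeared when 1 library was left out, with 2 genes in clusters 0 and 1 without young replicate 2 (Stmn1 and Ifi27l2a). In cluster 3, leaving out an aged library left 1 aged library. Without aged replicate 2 the log2 fold change of Ccl21a was -8.57. Without aged replicate 3 those of Xist and Myl10 were -10.6 and -3.24. The Xist value follows the split of sex-linked transcripts by replicate number, since aged replicate 2 had 0 Xist UMIs, and cannot be read as a change with age.

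The age effect did not differ detectably between cluster 3 and clusters 0 and 1. The edgeR interaction test called 0 of 4479 genes, with 200 at an unadjusted p under 0.05. The 5 genes of smallest p were Nipsnap3b (difference of log2 fold changes 1.83), Mycbp (2.33), Plac8 (0.94), Fos (-1.83) and Il7r (1.39). Without young replicate 2 it called 3 genes (Plac8, Cd24a and Malat1) and without aged replicate 3 it called 1 (Vpreb1).

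Young replicate 1 differed from the other 4 libraries in composition. Dividing clusters held 83.4% of its B-lineage cells (95% interval 80.4 to 86.0), against 10.8% and 10.97% in young replicates 2 and 3 and 12.1% and 9.84% in aged replicates 2 and 3 (exact permutation p = 0.8 for age). After thinning, 60.5% of its B-lineage cells were cycling, against 8.07%, 6.13%, 5.34% and 6.99% in the same order (exact permutation p = 0.6), and without thinning 81.2% against 9.61% to 13.5%. Without young replicate 1 the aged minus young difference was 0.107 points for dividing clusters and -0.934 points for cycling cells, against -24.1 and -18.7 with it.

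Neutrophil-like cells, led by the granule genes Elane, Mpo, Prtn3 and Ctsg and by S100a8, were 19.6% of young replicate 1 (174 of 890). They were 0.885% and 1.58% of young replicates 2 and 3, 0 of 282 cells in aged replicate 2 (up to 1.06%) and 1.99% of aged replicate 3 (exact permutation p = 0.7 for age). Elane had a UMI in 63.0% of these cells (median 9427 UMIs), 1.77% of non-dividing and 22.7% of dividing B-lineage cells (median 4349 UMIs). S100a8 had a UMI in 21.7% of them, and Ngp and Camp, of later neutrophil granules, in 7.94% and 5.82%. The cluster also held Mcpt8, a basophil gene, in 25.4% of cells and the monocyte genes Ccr2 and Csf1r in 30.2% and 29.6%. By the rule of 10% of cells, 4 neutrophil, 5 monocyte, 6 progenitor and 4 basophil markers were detected, from lists of different length. The neutrophil and monocyte lists are equally long and the progenitor and basophil lists shorter, so the neutrophil list was the least covered of these. Also detected were 7 of the 8 B cell markers, with Ebf1 in 63.5% of cells and in 18.0% after thinning. The cluster's 10 leading genes held 3 neutrophil and 1 basophil marker. The name of the class rests on these leading genes and not on the coverage of the lists. Without young replicate 1 the difference was -0.239 points, against -6.34 with it. Cluster 3 was 33.9%, 12.6% and 29.3% of non-dividing B-lineage cells in the young and 25.5% and 22.7% in the aged libraries (exact permutation p = 1).

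**Figure D3:**
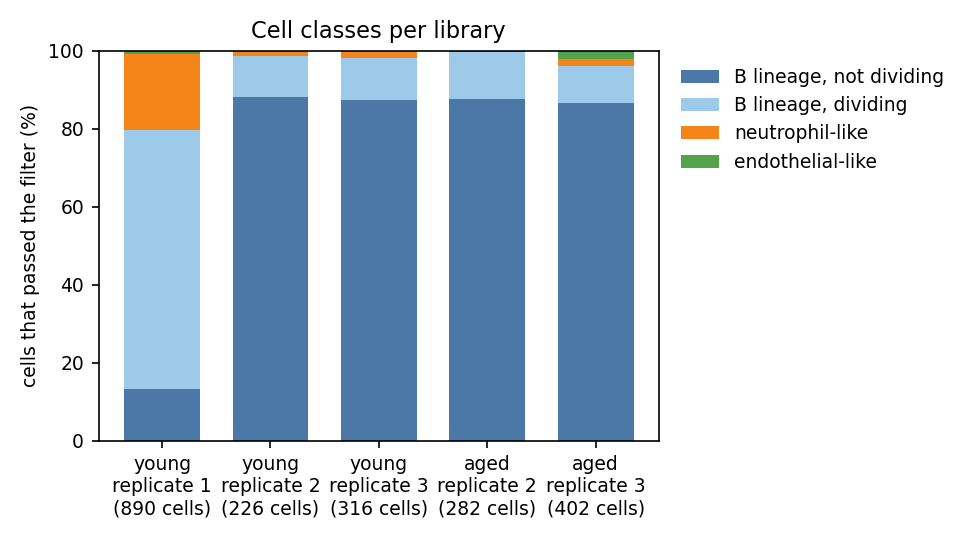
Share (%) of the cells that passed the filter in each of 4 classes, with 1 stacked bar per library and the number of cells under it. Young replicate 1 holds 19.6% neutrophil-like cells, and the other 4 libraries hold 0 to 1.99%.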

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

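The tests of free RNA, of the filter, of Pecam1, of doublets and of shared barcodes were chosen after the results were seen, and the test of depth in young replicate 1 was written before its value was seen.

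Among the 1268 barcodes below the filter, which no comparison uses, 8 (0.631%, 95% interval 0.273 to 1.24) held at least 3 markers of bone-forming cells, above the 0.237% that a count of 0 would allow. All 8 came from young replicate 2, which held 329 barcodes, 226 of them above the filter. The share pooled over the libraries is therefore lower than the share in that library. Over all libraries 9 of the 2116 barcodes above the filter also held 3, a share within the pooled interval.

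Libraries sorted as CD45-negative and CD31-positive held mostly B-lineage cells. Whether free B-lineage RNA filled barcodes of other cells was not decided. The 8 B cell markers reached at most 20.7% of their B-lineage level in endothelial-like cells. The 95% counting interval was 14.8 to 28.2 in young replicate 1, and the level was 6.85% in aged replicate 3. These cells were set apart by their expression, and a barcode holding mostly B-lineage RNA would have joined the B-lineage clusters. The values therefore describe the endothelial-like cells only. The bound of 50% for this test was set after the value was seen. It replaced an earlier one of 25%, which 20.7% meets and the upper end of the interval does not. Removal of an endothelial majority by the filter is argued against. Of the 1268 barcodes below it, 59.9% held at least 3 of the 8 B cell markers and 0.315% at least 3 of 11 endothelial markers. The endothelial share was 0.945% above the filter, but the shares below and above were not matched for depth, which favours detection above it. B-lineage cells that transcribe Pecam1 may have passed the CD31 side of the gate, since 10.7% of thinned B-lineage cells held a Pecam1 UMI against 1.68% for the highest of 11 other endothelial markers (Erg and Eng, left out of the 11, had a UMI in 7.24% and 4.46% of thinned non-dividing cells, against 13.2% for Pecam1). How they passed the CD45 side stays open, since Ptprc, the gene of CD45, had a UMI in 13.9% of thinned non-dividing and 10.1% of thinned dividing B-lineage cells, against 13.2% and 6.66% for Pecam1; the files hold no protein level, and an effect of freezing on the mixture of cells was not tested.

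Young replicate 1 held more dividing B-lineage cells and more neutrophil-like cells than the other libraries. For the dividing cells its greater depth is argued against, since 60.5% of its B-lineage cells were cycling after thinning to equal depth and the upper bound of the highest other library was 12.5%, and for the neutrophil-like cells depth was not tested. Free granule RNA in B-lineage cells is argued against only as the source of the neutrophil-like class. Those cells held B cell markers at 7.31% of the level in the B-lineage cells of young replicate 1. They were set apart by their expression, so this value does not bear on granule RNA within the B-lineage clusters. There Elane had a UMI in 22.7% of dividing cells over all libraries. Doublets with B-lineage cells are argued against as the source of the class by the same 7.31% (upper counting bound 7.75%), since 1 B-lineage cell of median depth would bring 39.2% of the median UMIs; this replaced a test by the doublet caller, which decided nothing as it marked 0.575% of these cells and 0.299% of the library's barcodes. No other library came from replicate number 1, so a difference of that preparation and a difference between animals remain open and untested.

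Libraries of 1 replicate number shared cell barcodes: 11 for number 2 and 9 for number 3, against 6 over the 8 other pairs of libraries. Chance reuse of a barcode is argued against, since a median of 95.8% of the genes of the copy with fewer UMIs were found in its partner, against a median of 64.8% and an upper 95% bound of 68.2% in matched draws. Molecules assigned to the wrong library of the pair are a candidate explanation, since 18 of the 20 copies had under 15% of the partner's UMIs and over 80% of their genes in it. Of these copies 3 passed the filter, and no biological explanation was tested.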

How the results depend on the processing

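The term for sex-linked transcripts, the removal of swapped copies, the naming of cells by 3 of 11 markers and all alternatives for the B-lineage, neutrophil-like and cluster 3 results were chosen after the data were seen. The stricter cell filter left no endothelial-like cells, so it gave no endothelial gene, list or cycling value. The sinusoidal and arterial comparisons, their difference, the arterial share and all of their alternatives also gave no value.

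In endothelial-like cells, where Aqp1 was called, 0 genes were called with DESeq2, with no filter on low counts or with every deposited barcode. Thinning cells to 1000 UMIs (which left 3 genes to test), limma on mean log values, and leaving out haemoglobin and mitochondrial genes also gave 0. Over all cells that passed the filter 0 genes were called in the main fit. There 11 genes were called with no filter on low counts, Aqp1 among them (log2 fold change 3.49), and 19 with the replicate number as a block. With a term for sex-linked transcripts 4 genes were called in endothelial-like cells (Aqp1, Cav1, Cd36 and Cst3). At resolution 1.2 the 1 gene called was S100a6 (log2 fold change 2.39, adjusted p = 0.0475) and not Aqp1. Without 1 library the count lay between 0 and 1. In non-dividing B-lineage cells 11 genes were called with no filter on low counts and 0 without any 1 library, and in clusters 0 and 1 there were 5 with no filter. The interaction gave 1 gene (Spp1) with every deposited barcode. Without 1 library the counts lay between 0 and 2 for cluster 3, 0 and 2 for clusters 0 and 1 and 0 and 3 for the interaction. Apart from Xist in cluster 3, which followed the split of sex-linked transcripts, the cause of these changes was not tested.

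With an estimated correlation or with fry, 0 gene lists were called in endothelial-like and 0 in non-dividing B-lineage cells, where camera had called 1 and 5. With doublets left out it called 1 and 6, and with every deposited barcode 2 and 9 (arterial markers in endothelial-like cells were not called, adjusted p = 0.0876), and with the term for sex-linked transcripts 3 in B-lineage cells. Without 1 library the count ranged from 1 to 3 and from 0 to 9.

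The labels give young and aged libraries the same replicate numbers and do not say what a number marks, while shared barcodes and sex-linked transcripts also followed it. Deviations of same-numbered libraries from their group means had a correlation across 5326 genes of 0.252 for number 2 and 0.149 for number 3. With 2 aged libraries these deviations mirror each other, and genes are not independent. With the replicate number as a block, Aqp1 in endothelial-like cells was at 4.63 (adjusted p = 0.784), and edgeR called 0 genes there, 28 in non-dividing B-lineage cells (3 higher and 25 lower), 4 in cluster 3 and 1 in clusters 0 and 1, and camera called 3 lists in B-lineage cells (MHC class II, unfolded protein response and heat shock). The 28 included Cd74, Ms4a1, Ifi27l2a and H2-Ab1, which were picked after their values were seen. Only 2 same-numbered pairs inform this fit, and they differed: young and aged Cd74 was at 1761 and 512 CPM in number 2 and 1683 and 1635 in number 3, and Ms4a1 at 248 and 15.2, and 78.6 and 71.1. Under the block the oxidative phosphorylation and ribosomal lists turned to higher values (adjusted p = 0.471 for both).

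For shares, the aged minus young difference of non-endothelial cells was -1.66 points with every deposited barcode and between -1.47 and 0.161 without 1 library. That of cycling endothelial-like cells was 30 points with every deposited barcode, -4.76 without thinning and -8.04 with 1 cycle gene required (0 in the main analysis). That of cluster 3 was 9.24 points at resolution 0.4, against -1.17. The cause was not tested.

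The named genes were picked for small p or large change in the main fit to the same libraries, so their direction was largely set in advance. They numbered 65, counted per comparison. Of their 1027 values under alternatives, 1026 kept their direction, 26 came past the threshold and 8, all of Aqp1, no longer passed. The exception was Sparc in endothelial-like cells, at 0.65 without aged replicate 3 and -1.74 without aged replicate 2, against -0.79.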

Other observations

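The tests and values in this part were chosen after the data were seen, and no explanation was tested for them.

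Cluster 7 was led by Rpl3l, the Y-linked Eif2s3y, Tmem164 and the recombination gene Rag2. It took 64 of its 87 cells from aged replicate 2, and 7 of its cells were called doublets. It was 25.9% of the non-dividing B-lineage cells of that library and 0 to 4.35% in the other libraries. Clusters 0 and 1 followed the replicate number, as sex-linked transcripts did, and Eif2s3y was also among the leading genes of cluster 1. Cluster 1 was 64.8% and 34.8% of these cells in young and aged replicate 2, and 19.5%, 9.06% and 15.5% in young replicates 1 and 3 and aged replicate 3.

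In endothelial-like cells 4 genes were picked after their values were seen. Cxcl12, a chemokine that retains stem cells in marrow, had a UMI in 66.7% of them and in 0.168% of non-dividing B-lineage cells. Kitl, the ligand of the stem cell receptor KIT, had a UMI in 38.9% against 0.0842%. Sox17, a transcription factor of arterial endothelium, had one in 55.6% against 0 of 1188, which allows up to 0.253% of cells with a UMI and does not limit the share that express it. Vcam1, an adhesion molecule, had a UMI in 1 of 18 endothelial-like cells and 1.18% of non-dividing B-lineage cells.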
